A study of Homo sapiens with 10 samples.

How the data were processed

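The per-array table holds 1 intensity value per probe and array, produced by the authors with GenomeStudio according to the submitters' processing notes; its version is not given in the sources used here. As deposited these intensities are on a linear scale, were not normalised between arrays and had no background subtracted, as read from the values. A second deposited table holds day averages for days 0, 20 and 35, each within 0.075 of the plain mean of that day's arrays, with a detection p-value for each average that the authors' software made, as the file header states.

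The array has 47227 probes. A single gene symbol was found for 30111 of them, 8 had several symbols and 17108 were unnamed here. For 30072 probes the symbol was joined by Entrez identifier. Intensities were corrected for background by the normexp method with an offset of 50 and quantile normalised in limma 3.58.1 under R 4.3.3, and analysed as log2 values. A probe counted as detected on an array when it lay above the percentile 95 of 582 probes for olfactory receptor, keratin-associated protein and taste receptor genes on that array. Probes detected on every array of at least 1 day were kept, which left 25253. Technical repeat arrays were averaged, so the fit used 6 samples in 4 groups, and each comparison was a contrast of group means with limma's moderated test and a trend of the variance on the mean level. The residual degrees of freedom were 2. For each gene the kept probe with the highest mean level was used, which gave 13984 genes, and p-values were adjusted over them by the Benjamini-Hochberg method in each comparison, with a call at an adjusted p under 0.05.

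The 23 gene lists held 496 genes, of which 459 had a probe on the array. List tests used limma's camera with a preset correlation of 0.01 between genes, adjusted by Benjamini-Hochberg over the lists, and again with the correlation estimated from the data. No camera call held with the estimated correlation, where the lowest adjusted p was 0.141. That form of the test has only the 2 residual degrees of freedom, all from the day 20 samples. Small p-values are hard to reach with it, so a lost call does not show that a list was unchanged. The groups, the lists, the settings, most of the other settings tried and the rule for naming genes were fixed before the data were examined. That rule named NKX2-1, the 10 largest rises and 10 largest falls among called genes for which each day 20 sample lay on the same side of every array of the other day, and up to 4 measured members of each list with the largest absolute difference. Genes outside the rule are described as named after their values were seen. In a fit to simulated data with known differences of 1 and 2 log2 units, 6.32% and 84.8% of the changed genes were called at day 20 against day 0. These shares were 1.02% and 23.5% at day 35 and 1.01% and 46.9% at day 55 against day 0. They were 2.00% and 75.5% at day 35 and 12.0% and 87.5% at day 55 against day 20, and 2.02% and 59.8% at day 55 against day 35. In the same order of comparisons, false calls were 3 of 93, 1 of 25, 8 of 55, 10 of 86, 11 of 107 and 5 of 65 calls, over 5% in the last 4. Each comparison was a single draw with few changed genes, such as 95 and 99 at day 20 against day 0. The changed genes were drawn from those of middle day 20 level, above the detection thresholds, and all others had no difference. In the data 19.9% of genes were called at day 20 against day 0, which loosens the Benjamini-Hochberg cutoff, and some named genes lie near the threshold. The shares are therefore not the power of the comparisons reported here. Differences in these shares between comparisons of 1 sample against 1 may reflect the draw alone. Every sample was simulated with the spread of the fit, so whether single samples vary like those of day 20 was not tested.

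Alternatives covered the background correction, the normalisation between arrays, the filter on dim probes, the use of technical repeats, the variance model, the probe that stands for a gene, the threshold and leaving out each replicate array in turn. Alternatives chosen after seeing the data were values raised to the detection threshold, the authors' detection p as filter, the 28S signal as a covariate and comparisons between samples with a like 28S signal. Probes without a single gene name were left out of gene counts. Figures were drawn from the same result tables.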

Results

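Total RNA was profiled on Illumina bead arrays from human embryonic stem cells that carry GFP in the NKX2-1 locus. GFP-positive cells were sorted after 20, 35 and 55 days of differentiation and set against the undifferentiated cells of day 0. NKX2-1 is a homeodomain transcription factor of the ventral forebrain, where the medial ganglionic eminence (MGE) gives rise to cortical interneurons. The medium held B27, a BMP receptor trap (BMPRIA-Fc), the activin and NODAL receptor inhibitor SB431542, the WNT antagonist DKK1, the ROCK inhibitor Y27632 and the Hedgehog agonist purmorphamine. The 10 arrays came from 6 independent samples. Day 0 was 1 sample on 4 technical repeat arrays, though the design text gives 3 technical replicates for it. Day 20 was 3 samples on 1 array each, day 35 was 1 sample on 2 technical repeat arrays and day 55 was 1 sample on 1 array. Sample labels name the sort for every day, day 0 included, while the design text names it for the differentiated cells.

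The median deposited intensity per array lay between 131.6 and 206.8, and between 43.3% and 49.2% of the 47227 probes lay above an array's detection threshold. Across probes, log2 values of the 3 day 20 samples correlated at r between 0.956 and 0.978, and those of the day 0 technical repeats at 0.986 to 0.993. Day 0 arrays 1 and 3 (r 0.993) and 2 and 4 (r 0.992) were closer than the other pairs (0.986 to 0.987). Whether these pairs were prepared apart was not tested. Probes are not independent replicates. After background correction and before quantile normalisation, probes for genes silent in these cells spread more widely at day 0 than on the other arrays. The SD, estimated from the median absolute deviation, was 0.35 to 0.42 against 0.16 to 0.19 on the log2 scale. After normalisation the detection thresholds were 6.72 to 6.78 at day 0 and 6.64 to 6.70 on the other arrays. A probe for 28S ribosomal RNA (RNA28SN5) varied between samples of the same day. Its log2 signal was 12.41, 14.59 and 6.82 in day 20 samples 1, 2 and 3, 14.96 and 15.01 on the day 35 arrays, 7.46 at day 55, and 6.48, 10.16, 6.23 and 10.61 on day 0 arrays 1 to 4, which splits them into the same pairs. A probe for 18S ribosomal RNA (RNA18SN5) read 12.97, 14.28 and 8.13 in day 20 samples 1, 2 and 3, 8.38 and 9.38 on the day 35 arrays and 7.89 at day 55, so day 35 was high in 28S and low in 18S. Only day 20 had independent samples, so every gene p-value below rests on the spread among the 3 day 20 samples. The moderated test weighs that spread with a prior over all probes, of 5.89 degrees of freedom against 2 residual ones. Single samples of the other days are assumed to vary like those of day 20. Camera p-values with the preset correlation set list genes against the other genes and do not measure spread between samples. The number of arrays limits the precision of each value.

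Day 20 against day 0 asked how the sorted cells differed from the pluripotent cells they came from. The day 20 cells were sorted for GFP from the NKX2-1 locus, so a higher NKX2-1 level was selected for. Its test is a check of the sort and not a finding. The cells of the later days were sorted in the same way, so their NKX2-1 expression was selected for too. NKX2-1, the gene that carries the reporter, was at least 24.9-fold higher at day 20 (log2 difference 5.37, SE 0.33, 3 samples against 1, higher in 3 of 3; limma, Benjamini-Hochberg adjusted p = 9.86e-05). A fold given as at least a value is computed against the detection threshold of the dimmer day, with that day's values raised to the threshold where only some of its arrays lay above it. The largest rise was that of DLK1, a transmembrane protein related to Notch ligands, at least 240-fold (log2 8.10, SE 0.21), with day 0 above the threshold on 1 of 4 arrays. HES5, a Notch effector of neural progenitors, rose at least 145-fold (log2 7.19, SE 0.29), and SIX6, a transcription factor of the eye field and hypothalamus, rose at least 87.3-fold (log2 6.66, SE 0.31), each with day 0 detected on some arrays only (3 of 4 and 1 of 4). Among the largest falls, the metallothionein MT1G was at least 110-fold lower (log2 -7.14, SE 0.31) and the pluripotency factor POU5F1 at least 57.6-fold lower (log2 -6.37, SE 0.27).

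Of the 25 measured pluripotency genes, 22 fell and 3 were without a call, with 23 falling when adjusted over the list alone. ZFP42 was at least 56.3-fold lower and the adhesion molecule EPCAM 52.0-fold lower. The median of that list was -3.02 (log2), or -2.76 with genes under the detection threshold at their bound, and camera gave an adjusted p of 3.34e-22 (limma, Benjamini-Hochberg over the 23 lists). It was an adjusted p = 0.183 with an estimated correlation. Of 7 activin and NODAL targets 5 fell, as when adjusted over the list alone. Among these LEFTY1, a NODAL antagonist, had a log2 difference of -4.91 and LEFTY2 was at least 32.2-fold lower (limma camera adjusted p = 6.97e-07, and adjusted p = 0.314 with an estimated correlation). In the neural progenitor and radial glia list 14 of 24 genes rose and 1 fell (17 and 1 adjusted over the list alone). The Notch ligands DLL3 and DLL1 rose 17.2-fold and 15.7-fold and the fatty acid binding protein FABP7 18.7-fold (limma camera adjusted p = 5.06e-08, and adjusted p = 0.320 with an estimated correlation). Of 30 genes for neuronal cytoskeleton and differentiation, 19 rose and 11 had no call (22 rose and 1 fell adjusted over the list alone). The stathmin STMN2 rose 20.6-fold, TAGLN3 21.2-fold and the neuronal RNA-binding protein ELAVL4 at least 9.63-fold (limma camera adjusted p = 1.54e-08, and adjusted p = 0.314 with an estimated correlation).

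Of 20 MGE transcription factors, 7 rose and 13 had no call (8 rose adjusted over the list alone). NKX2-1, for which the cells were sorted, is among the 7, and the list test includes it. The same applies to this list at the later days against day 0. Besides NKX2-1, SIX3 rose at least 43.9-fold, LMO3 at least 21.9-fold and DLX1, a factor of GABA neuron precursors, at least 8.22-fold (1 of 4 day 0 arrays above the threshold; limma camera adjusted p = 0.000264, and adjusted p = 0.320 with an estimated correlation). In the list for the hypothalamus and other NKX2-1 forebrain, 6 of 13 genes rose and 1 fell (7 and 1 adjusted over the list alone). NKX2-2, a ventral target of Hedgehog signalling, rose at least 39.0-fold (1 of 4 day 0 arrays) and the hypothalamic factor OTP at least 4.83-fold (3 of 4), while FOXD1 fell 5.15-fold (limma camera adjusted p = 0.0158, and adjusted p = 0.320 with an estimated correlation). Among 10 Hedgehog pathway genes 3 rose and 1 fell (3 and 2 adjusted over the list alone). The Hedgehog receptor and target PTCH1 rose 7.63-fold (log2 2.93, SE 0.41) and FOXA2, a floor plate factor, 5.80-fold (log2 2.54, SE 0.55), and GLI2 fell 2.35-fold (limma camera adjusted p = 0.226). Of 18 genes for interneuron GABA synthesis, peptides and subtypes, 2 rose and 3 fell (5 and 3 adjusted over the list alone). GAD1, a GABA-synthesising enzyme, rose 12.7-fold and the serotonin receptor HTR3A was at least 5.87-fold lower (limma camera adjusted p = 0.571). In the synapse, receptors and channels list 9 of 36 rose and 2 fell (11 and 2 adjusted over the list alone). SNAP25, of the vesicle fusion machinery, rose at least 9.71-fold and the synaptotagmin SYT4 6.87-fold (limma camera adjusted p = 0.0158, and adjusted p = 0.320 with an estimated correlation). None of the 8 cholinergic genes was called by limma, with 2 higher at an unadjusted p under 0.05.

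Of 36 cell cycle genes 2 fell (CDT1, 4.42-fold, and BUB1, 2.93-fold), 11 were lower at an unadjusted p under 0.05, and adjusted over the list alone limma called 0 (limma camera adjusted p = 0.0139, and adjusted p = 0.731 with an estimated correlation). The mean level of that list was 10.66, 9.93 and 10.96 in day 20 samples 1, 2 and 3, against 11.08 at day 0, and sample 2, the lowest, had the highest 28S signal of the day. In the migration and guidance list 7 of 26 rose and 3 fell, with the guidance ligand SLIT2 at 7.64-fold and the chemokine receptor ACKR3 at 7.59-fold higher. Of 24 stress and dissociation genes 2 rose and 6 fell, among them the immediate early genes FOSB (7.91-fold lower) and FOS (4.71-fold lower). The mesoderm and endoderm list held 4 that rose and 5 that fell of 15, with AFP at least 6.14-fold lower (1 of 3 day 20 samples above the threshold) and ACTA2 4.84-fold higher. The astroglia and oligodendroglia list held 1 and 5 of 14, with APOE 5.00-fold lower. BMP targets gave 2 rises and 3 falls of 12 (ID3 3.82-fold higher, BAMBI at least 17.6-fold lower with 2 of 3 day 20 samples above the threshold). WNT targets gave 1 and 2 of 11 (CCND1 2.54-fold higher, AXIN2 3.66-fold lower). For the pallium and glutamatergic list 2 of 9 rose, LHX2 by at least 26.3-fold and FEZF2 by at least 5.82-fold. Thyroid and lung genes gave 1 rise, FOXA2, and 1 fall, the secretoglobin SCGB3A2 at 21.6-fold lower, of 5. Neural crest and peripheral neurons gave 1 rise of 8, SNAI2, at least 1.30-fold. Of 22 hypoxia and glycolysis genes 2 fell, ADM by 5.38-fold. The mean level of that list was 11.12, 10.08 and 11.22 in day 20 samples 1, 2 and 3, against 11.31 at day 0, so sample 2 stood apart here too. Of 13 housekeeping genes 1 fell, HPRT1 by 2.31-fold. For the midbrain, hindbrain and spinal cord list limma called 0 of 5 genes, with 1 higher and 1 lower at an unadjusted p under 0.05. Adjusted over the list alone, the counts of rises and falls were 7 and 4 for migration, 4 and 7 for stress, 4 and 5 for mesoderm, 1 and 5 for astroglia, 2 and 3 for BMP and 1 and 3 for WNT. They were 2 and 0 for pallium, 2 and 1 for thyroid, 2 and 0 for neural crest, 0 and 2 for hypoxia and 0 and 0 for housekeeping. Apart from the cell cycle list, the lists of this paragraph had camera adjusted p between 0.0757 and 0.801 (limma, Benjamini-Hochberg).

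Over all 13984 genes tested, 1531 rose and 1247 fell between day 0 and day 20 (limma, Benjamini-Hochberg adjusted p under 0.05). Of these, 320 rises and 272 falls had a bound as their fold, with no array of the dimmer day above the threshold. Called genes for which no fold could be given are not in such counts, here and below. With values raised to the detection threshold, a setting chosen after seeing the data, 647 rose and 920 fell, so rises made up 41.3% of the calls in place of 55.1%. Genes under the threshold in all 3 day 20 samples have no spread in that setting, so they are called more readily. Without day 20 sample 1 the counts were 682 and 639, and without sample 3 they were 2375 and 1925. Samples 2 and 3 were the least alike of day 20 (r 0.956), while sample 1 correlated at 0.978 with each. Leaving out sample 1 therefore left the spread to the least alike pair. Without sample 1 BUB1 (log2 -1.44), GLI2 (-1.13), HPRT1 (-1.27) and SNAI2 (1.21) had no call. Rises and falls without sample 1 were 5 and 2 in the synapse, receptors and channels list, 4 and 3 in migration and guidance, and 2 and 3 in mesoderm and endoderm. They were 1 and 1 in BMP targets and in the interneuron list, 1 and 4 in stress and dissociation, and 0 and 3 by limma in astroglia and oligodendroglia. Of WNT targets and of cell cycle genes 1 each fell then, and by limma 0 neural crest and 0 housekeeping genes were called. Without sample 2, 4 interneuron and 3 neural crest genes rose, 7 cell cycle genes fell, and hypoxia and glycolysis gave 3 rises and 4 falls. Without sample 3, 13 cell cycle, 8 hypoxia and glycolysis and 3 housekeeping genes fell. In that setting 4 of 5 thyroid and lung genes, 4 of 8 neural crest genes, 5 Hedgehog genes and 5 interneuron genes rose.

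**Figure D1:**
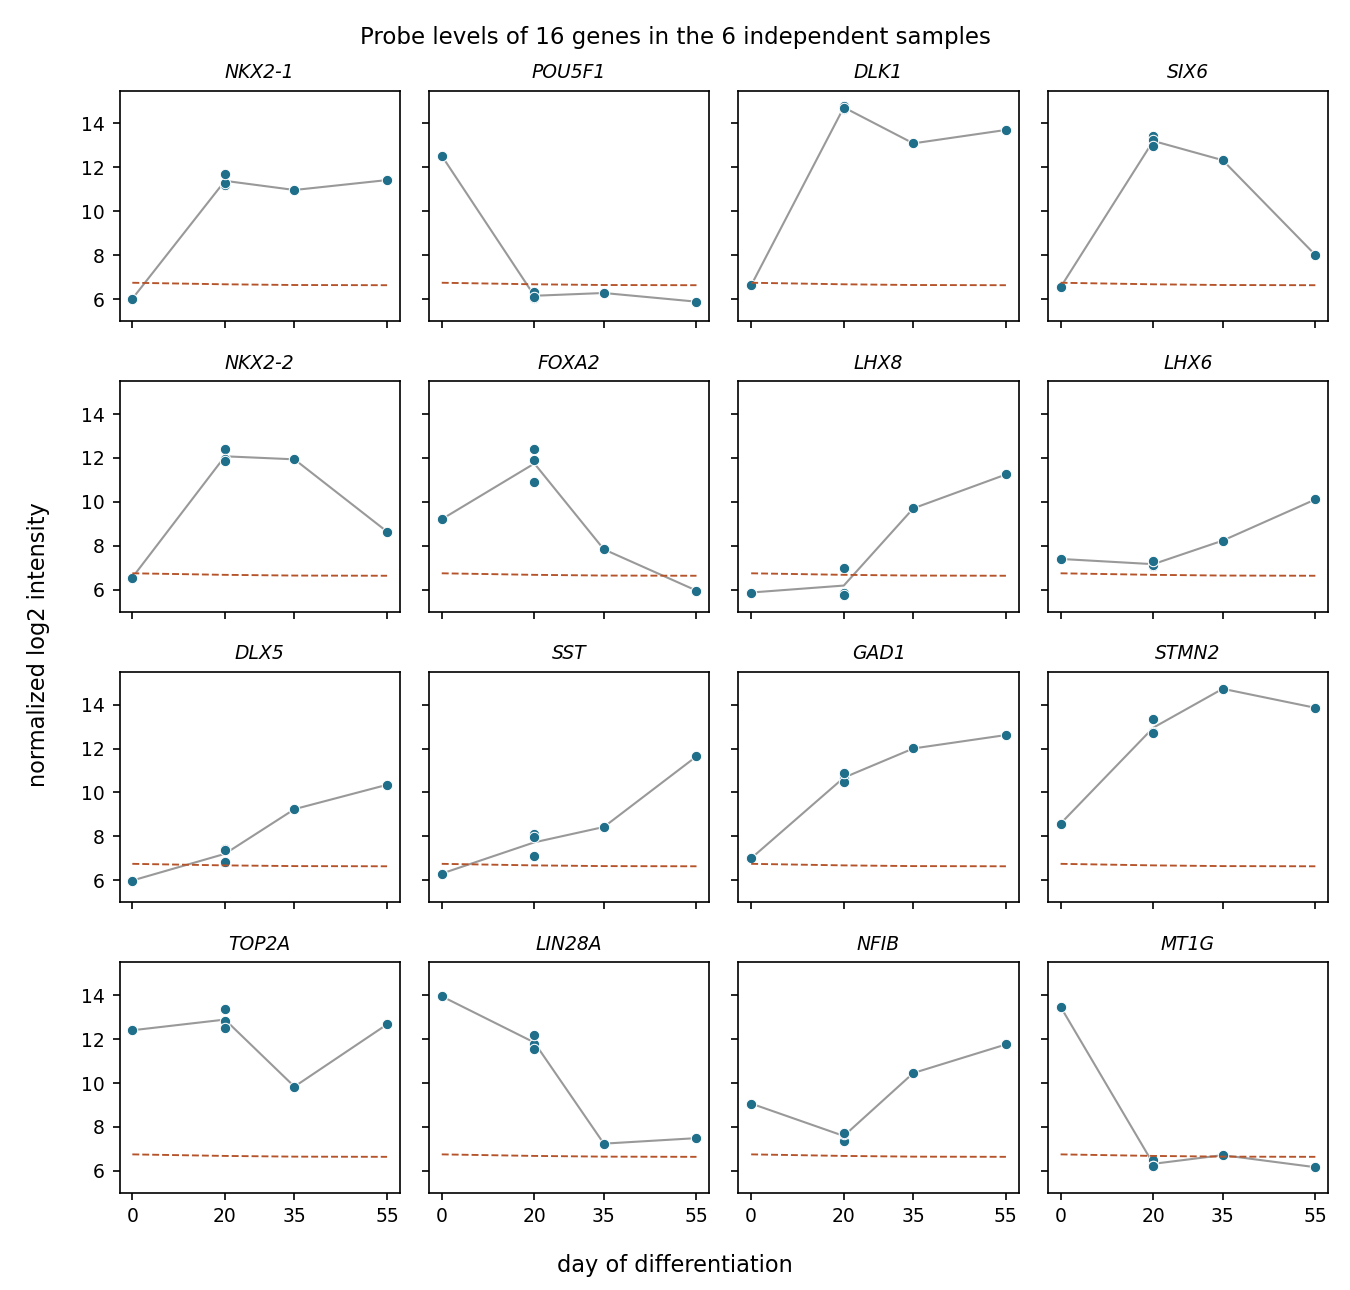
Log2 expression of named genes (vertical axes, log2 normalised intensity) at days 0, 20, 35 and 55 (horizontal axes). Cells of days 20, 35 and 55 were sorted for the reporter in NKX2-1. Points are independent samples with technical repeat arrays averaged, lines join the means of the days and dashed lines mark the detection threshold; NKX2-1 stays between 10.97 and 11.42 at the 3 later days, and TOP2A reads 9.84 at day 35 against a day 20 mean of 12.89.

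Day 35 against day 0 set 1 sample on 2 arrays against 1 sample on 4 arrays. A higher NKX2-1 level was selected for by the sort here too. NKX2-1 was at least 18.6-fold higher (log2 4.95, SE 0.41; limma, Benjamini-Hochberg adjusted p = 0.000394). RTN1, a reticulon of neurons, rose 139-fold (log2 7.12, SE 0.38) and STMN4, a stathmin, at least 74.5-fold (log2 6.53, SE 0.46), while LIN28A, an RNA-binding protein of pluripotent cells, fell 104-fold (log2 -6.70, SE 0.42). All 25 pluripotency genes fell, also when adjusted over the list alone, with L1TD1 at least 99.3-fold and the cadherin CDH1 at least 68.2-fold lower (limma camera adjusted p = 8.99e-23; limma, Benjamini-Hochberg; adjusted p = 0.170 with an estimated correlation).

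Of 30 genes for neuronal cytoskeleton and differentiation, 23 rose (26 adjusted over the list alone), with the microtubule protein MAPT at least 62.1-fold (1 of 4 day 0 arrays above the threshold) and STMN2 at 70.2-fold higher (limma camera adjusted p = 1.90e-15, and adjusted p = 0.170 with an estimated correlation). In the synapse, receptors and channels list 25 of 36 rose (27 adjusted over the list alone). SNAP25 rose at least 56.4-fold, the sodium channel SCN2A at least 23.5-fold and the glutamate receptor subunit GRIA2 at least 24.3-fold (limma camera adjusted p = 3.11e-10, and adjusted p = 0.170 with an estimated correlation). Of 18 interneuron genes 10 rose and 1 fell (11 and 1 adjusted over the list alone): GAD1 was 31.9-fold and the extracellular protein RELN at least 17.3-fold higher (limma camera adjusted p = 0.00207, and adjusted p = 0.431 with an estimated correlation). Of 8 cholinergic genes 5 rose (6 adjusted over the list alone), with the acetylcholine-degrading enzyme ACHE 20.6-fold and the LIM factor LHX8 at least 7.75-fold higher (limma camera adjusted p = 0.000362, and adjusted p = 0.260 with an estimated correlation). Of 20 MGE transcription factors 10 rose, also adjusted over the list alone, with DLX1 at least 25.2-fold higher (1 of 4 day 0 arrays; limma camera adjusted p = 5.93e-06, and adjusted p = 0.260 with an estimated correlation). In the list for the hypothalamus and other NKX2-1 forebrain 6 of 13 rose and 1 fell, also adjusted over the list alone. SIX6 was at least 47.6-fold higher (1 of 4 day 0 arrays) and the hypothalamic neuropeptides HCRT and TRH at least 6.25-fold and at least 4.18-fold higher (limma camera adjusted p = 0.00411, and adjusted p = 0.260 with an estimated correlation). Of 24 neural progenitor genes 10 rose and 1 fell (12 and 4 adjusted over the list alone), with the Notch target HEY1 at least 37.3-fold higher (limma camera adjusted p = 0.0127, and adjusted p = 0.449 with an estimated correlation).

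Of 36 cell cycle genes 29 fell, also when adjusted over the list alone, with the mitotic checkpoint kinase BUB1 lower by a log2 difference of -4.00 (SE 0.50) and the kinase CDK1 11.7-fold lower (limma camera adjusted p = 1.90e-15; limma, Benjamini-Hochberg; adjusted p = 0.449 with an estimated correlation). The list's mean level was 8.65 at day 35, the sample with the highest 28S signal. In the migration and guidance list 12 of 26 rose and 3 fell (16 and 4 adjusted over the list alone), with SLIT2 at 7.89-fold higher (limma camera adjusted p = 0.00789, and adjusted p = 0.431 with an estimated correlation). The cell cycle inhibitor CDKN1A rose 5.75-fold, tyrosine hydroxylase (TH) at least 8.75-fold, and the lipoprotein APOE fell 17.2-fold.

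In total 1975 genes rose and 1461 fell (limma, Benjamini-Hochberg), 481 and 331 of them with a bound as fold and no array of the dimmer day above the threshold. Rises made up 57.5% of these calls and 73.7% under median scaling of the arrays. Leaving out day 20 sample 1, which left the spread to the less alike samples 2 and 3, gave 1171 and 856, with 3 rises in the migration and guidance list. Without samples 2 and 3 in turn, 3 and 4 neural progenitor genes fell.

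**Figure D2:**
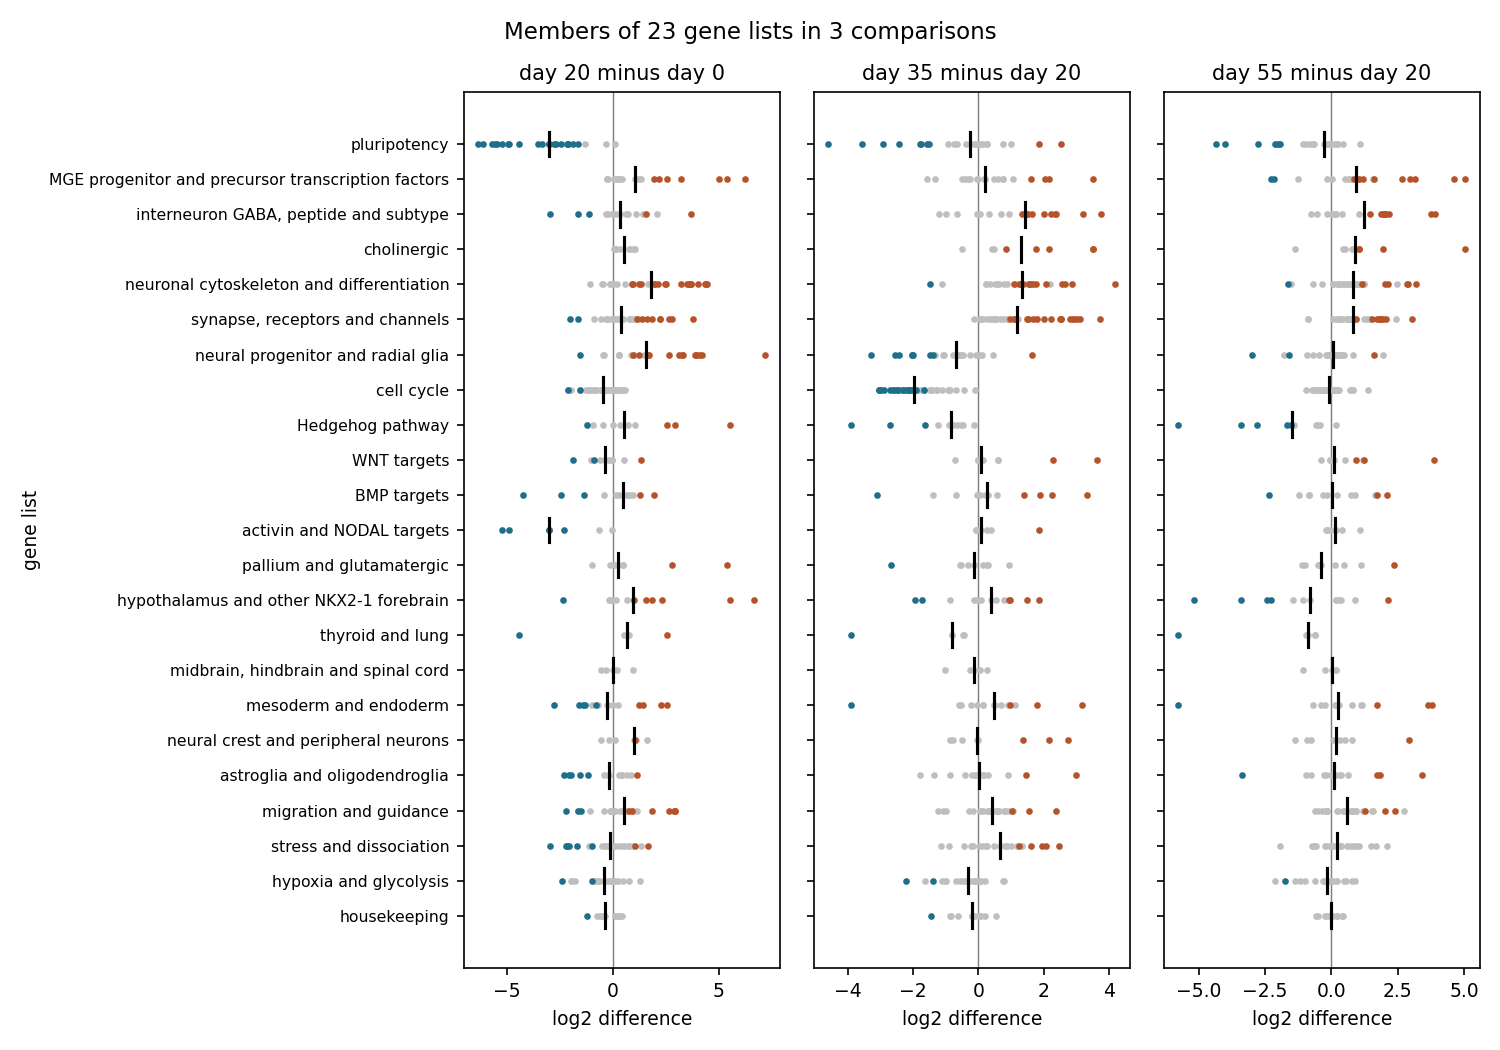
Log2 differences (horizontal axes, which differ in range between panels) of each measured member of the 23 fixed gene lists (vertical axis) at day 20 against day 0, day 35 against day 20 and day 55 against day 20. Orange points rose, blue points fell and grey points had no call (limma, Benjamini-Hochberg), and black bars are list medians; 22 pluripotency genes are blue in the first panel and 19 cell cycle genes in the middle one.

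Day 55 against day 0 compared 1 array with 1 sample on 4 arrays. The sort again selected for a higher NKX2-1 level. NKX2-1 was at least 25.5-fold higher (log2 5.40, SE 0.41; limma, Benjamini-Hochberg adjusted p = 0.000362). DLK1 rose at least 118-fold (log2 7.07, SE 0.26), OLIG1, a factor of ventral progenitors and oligodendrocyte precursors, at least 69.0-fold (log2 6.53, SE 0.48) and DLX1 at least 52.6-fold (log2 5.87, SE 0.48), with day 0 above the threshold on 1 of 4 arrays for DLK1 and DLX1. The neuropeptide somatostatin (SST), a marker of MGE-derived interneurons, rose at least 29.6-fold (log2 5.33, SE 0.56). L1TD1 was at least 99.9-fold lower (log2 -7.09, SE 0.49), and all 25 pluripotency genes fell, also adjusted over the list alone (limma camera adjusted p = 1.13e-28, and adjusted p = 0.141 with an estimated correlation).

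Of 20 MGE transcription factors 15 rose (17 adjusted over the list alone), LHX8 by at least 22.6-fold and LMO3 by at least 34.9-fold (limma camera adjusted p = 3.00e-10, and adjusted p = 0.215 with an estimated correlation). Of 18 interneuron genes 8 rose and 1 fell, the same numbers as when adjusted over the list alone, with GAD1 48.8-fold and the vesicular GABA transporter SLC32A1 at least 11.8-fold higher (1 of 4 day 0 arrays; limma camera adjusted p = 0.000902, and adjusted p = 0.397 with an estimated correlation). For neuronal cytoskeleton and differentiation 21 of 30 rose (25 adjusted over the list alone), MAPT by at least 42.7-fold (1 of 4 day 0 arrays; limma camera adjusted p = 2.68e-15, and adjusted p = 0.171 with an estimated correlation). In the synapse, receptors and channels list 20 of 36 rose (23 adjusted over the list alone), with the vesicle protein SYP at least 19.2-fold higher (3 of 4 day 0 arrays; limma camera adjusted p = 2.41e-09, and adjusted p = 0.171 with an estimated correlation). Of 24 neural progenitor genes 14 rose and 1 fell (15 and 1 adjusted over the list alone), with HES5 at least 77.0-fold (3 of 4 day 0 arrays) and FABP7 32.4-fold higher (limma camera adjusted p = 3.42e-07, and adjusted p = 0.287 with an estimated correlation).

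Among 10 Hedgehog pathway genes 1 rose and 4 fell, also adjusted over the list alone: the transcriptional effector GLI1 was at least 3.70-fold, GLI2 6.31-fold and FOXA2 at least 5.94-fold lower (limma camera adjusted p = 0.0920; limma, Benjamini-Hochberg). In the list for the hypothalamus and other NKX2-1 forebrain 3 of 13 rose and 1 fell (4 and 1 adjusted over the list alone), with TRH at least 5.10-fold higher and SIX6 at least 2.40-fold higher (1 of 4 day 0 arrays; limma camera adjusted p = 0.351). The SIX6 call (log2 1.47, adjusted p = 0.0354) was lost without background correction (1.07, adjusted p = 0.0896), under cyclic loess (1.33, 0.0744) and with values raised to the detection threshold (1.37, 0.0840; limma). It was also lost with all probes tested and with the first array of each sample (adjusted p = 0.0518 and 0.0526, limma). Of 26 migration and guidance genes 13 rose and 2 fell (14 and 3 adjusted over the list alone), with the ephrin receptors EPHB1 and EPHA4 each 10.6-fold higher (limma camera adjusted p = 0.000310, and adjusted p = 0.287 with an estimated correlation). In the mesoderm and endoderm list 5 rose and 4 fell of 15 (5 and 5 adjusted over the list alone), the collagen COL3A1 by at least 12.5-fold and the proteoglycan DCN by at least 8.03-fold. With the authors' detection p as filter, a setting chosen after seeing the data, another DCN probe gave -0.50 without a call. That filter has no detection p for day 55, so it drops the main DCN probe, detected at day 55 alone. A further DCN probe read 6.32 at day 0 and 7.11 at day 55, above the threshold at day 55 only. The remaining DCN probe, at 6.52 and 6.42, was below the threshold on every array. Cell cycle genes gave 2 falls of 36, with BUB1 3.56-fold lower, and 10 were lower at an unadjusted p under 0.05 while limma called 0 adjusted over the list alone (camera adjusted p = 0.00191, and adjusted p = 0.7003 with an estimated correlation). The 28S signal at day 55 was 7.46. APOE fell 51.9-fold.

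Of all genes tested 1282 rose and 954 fell (limma, Benjamini-Hochberg), 358 and 351 of them with a bound as fold and no array of the dimmer day above the threshold. Rises made up 57.3% of these calls and 69.5% under median scaling. Without day 20 sample 1 the counts were 668 and 558, with 11 rises in the synapse, receptors and channels list and 8 among migration and guidance genes, and BUB1 (log2 -1.82) and SIX6 (1.49) had no call, nor by limma any cell cycle gene. Without sample 3, 1994 genes rose and 8 cell cycle genes fell, as 8 did without sample 2.

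Day 35 against day 20 compared 1 sample with 3. The activin and BMP antagonist FST rose 48.2-fold (log2 5.59, SE 0.33; limma, Benjamini-Hochberg adjusted p = 0.00170), above the level of each day 20 sample. The growth cone protein GAP43 rose 18.3-fold (log2 4.19, SE 0.33), the potassium channel KCNJ6 at least 23.2-fold (log2 4.64, SE 0.33; above the threshold in 1 of 3 day 20 samples) and the granin SCG2 22.4-fold (log2 4.48, SE 0.31). LIN28A fell 24.3-fold (log2 -4.60, SE 0.34), gastrin-releasing peptide (GRP) 22.3-fold, the growth factor FGF8 16.2-fold, and FOXA2 fell by a log2 difference of -3.91 (SE 0.55). NKX2-1 did not pass limma's test (log2 -0.42, SE 0.33, adjusted p = 0.543), and its expression was selected for by the sort on both days.

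Of 36 cell cycle genes 19 fell (29 adjusted over the list alone): the topoisomerase TOP2A was 8.28-fold lower (log2 -3.05, SE 0.35), cyclin CCNB2 8.18-fold, the mitotic kinase AURKB 7.94-fold and the ubiquitin-conjugating enzyme UBE2C 7.47-fold. The median of the list was -1.97 (log2), and 32 members were lower at day 35 than in each day 20 sample. Camera gave an adjusted p of 4.64e-21 (limma, Benjamini-Hochberg), against an adjusted p = 0.394 with an estimated correlation. Among the 5 differentiated samples the list's mean level was lowest, at 8.65, in the day 35 sample with its high 28S signal, and second lowest, at 9.93, in day 20 sample 2, which had the second highest. Against the 2 day 20 samples with a 28S signal above 10 the list's median difference was -1.76, and against the 1 with a low signal, which also had the 18S signal nearest to that of day 35, it was -2.34. No day 20 sample had a high 28S with a low 18S signal, as at day 35. In the neural progenitor and radial glia list 8 of 24 fell and 1 rose (9 and 1 adjusted over the list alone), with the Notch targets HES1 9.69-fold and HES5 5.84-fold lower (limma camera adjusted p = 2.12e-06, and adjusted p = 0.320 with an estimated correlation).

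In the synapse, receptors and channels list 18 of 36 rose (24 adjusted over the list alone), SCN2A by 13.3-fold and the sodium channel SCN9A by at least 7.58-fold (1 of 3 day 20 samples above the threshold; limma camera adjusted p = 1.67e-15, and adjusted p = 0.245 with an estimated correlation). For neuronal cytoskeleton and differentiation 15 of 30 rose and 1 fell (23 and 1 adjusted over the list alone), with the intermediate filament INA 7.30-fold and MAPT 6.32-fold higher (limma camera adjusted p = 3.89e-12, and adjusted p = 0.320 with an estimated correlation). Of 18 interneuron genes 10 rose (11 rose and 2 fell adjusted over the list alone), with RELN 13.5-fold, the cannabinoid receptor CNR1 9.28-fold and the peptide precursor TAC1 at least 4.87-fold higher (2 of 3 day 20 samples; limma camera adjusted p = 7.06e-06, and adjusted p = 0.320 with an estimated correlation). Of 8 cholinergic genes 5 rose (6 adjusted over the list alone), ACHE by 11.4-fold (limma camera adjusted p = 4.13e-05, and adjusted p = 0.320 with an estimated correlation). Of 20 MGE transcription factors 4 rose (7 rose and 2 fell adjusted over the list alone), LHX8 by at least 7.54-fold, with 1 of 3 day 20 samples above the threshold, and ISL1 by 4.45-fold (limma camera adjusted p = 0.0630). Among 10 Hedgehog pathway genes 3 fell (5 adjusted over the list alone), PTCH1 by 6.54-fold (limma camera adjusted p = 4.13e-05, and adjusted p = 0.320 with an estimated correlation). In the list for the hypothalamus and other NKX2-1 forebrain 4 of 13 rose and 2 fell (5 and 3 adjusted over the list alone), TRH by 3.64-fold higher and the eye field factor RAX at least 2.97-fold lower (limma camera adjusted p = 0.226). Of 24 stress and dissociation genes 5 rose (6 adjusted over the list alone), among them FOS at 5.53-fold and EGR1 at 4.17-fold (limma camera adjusted p = 0.00192, and adjusted p = 0.320 with an estimated correlation). RSPO3, a WNT agonist, was at least 11.4-fold higher and the BMP pseudoreceptor BAMBI at least 9.34-fold higher (2 of 3 day 20 samples), while the BMP target ID3 was 8.51-fold lower.

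Between day 20 and day 35, 708 genes rose and 414 fell (limma, Benjamini-Hochberg). A bound as fold, with no array of the dimmer day above the threshold, was given for 106 and 17. Rises made up 63.1% of these calls and 82.5% under median scaling, where 198 genes fell. With values raised to the detection threshold, a setting chosen after seeing the data, 626 rose and 83 fell (88.3% rises). That setting kept 387 of the 1122 calls, and in it genes under the threshold in all 3 day 20 samples have no spread. Without day 20 sample 1 the counts were 206 and 84, 750 genes fell without sample 2, and without sample 3 they were 1157 and 846. Without sample 1 the cell cycle list held 11 falls (32 without sample 2), the synapse, receptors and channels list 9 rises and the neuronal cytoskeleton list 4. The neural progenitor list then held 3 falls, the interneuron list 7 rises, the MGE list 1, the Hedgehog list 1 fall, and the stress and hypothalamus lists 0 rises by limma. EGR1 (log2 1.80), FOS (2.06), ISL1 (2.27), PTCH1 (-2.63) and TRH (1.92) then had no call. Without sample 2, 5 Hedgehog genes fell and 8 stress genes rose, and without sample 3, 23 cytoskeleton genes rose.

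**Figure D3:**
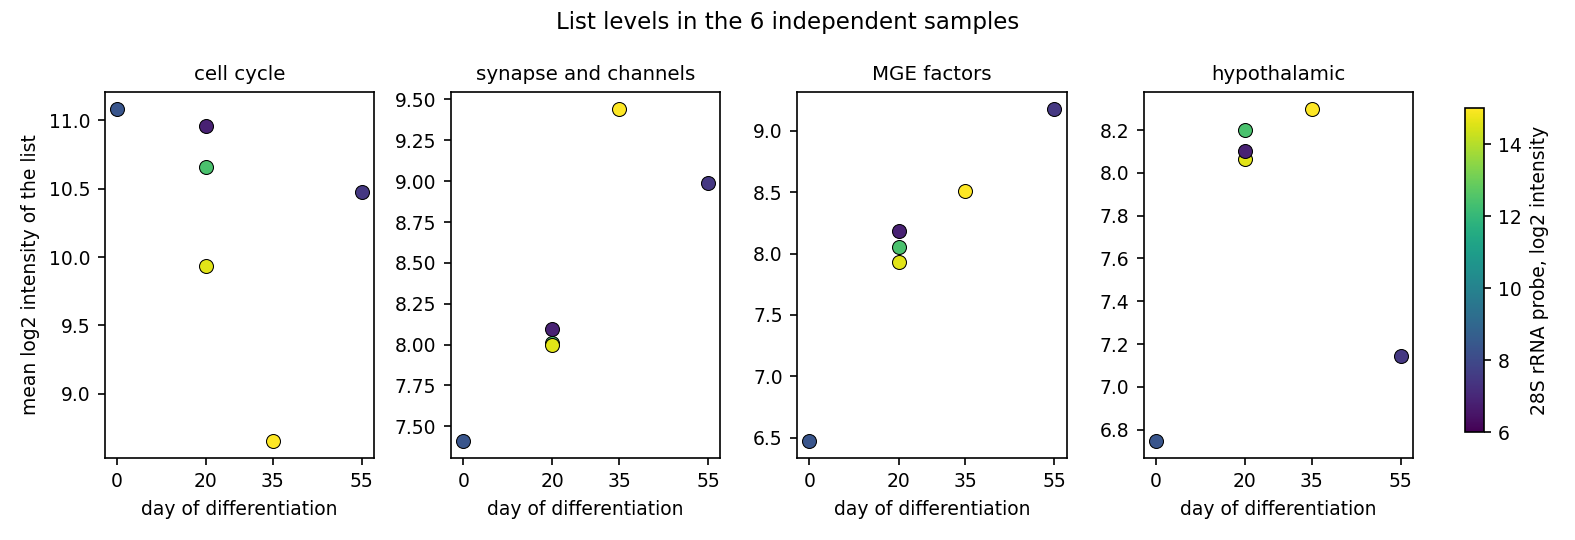
Mean log2 intensity (vertical axes) of the members of 4 gene lists in each of the 6 independent samples, by day of differentiation (horizontal axes); points are samples, coloured by the log2 signal of the 28S ribosomal RNA probe. The cell cycle list reads 8.65 at day 35 and 10.48 at day 55, against 9.93 to 10.96 in the day 20 samples.

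Day 55 against day 20 also compared 1 sample with 3. WLS, which carries WNT proteins to the cell surface, rose 52.0-fold (log2 5.70, SE 0.36; limma, Benjamini-Hochberg adjusted p = 0.00111), above each of the 3 day 20 samples. LHX8 rose at least 22.0-fold (log2 5.05, SE 0.50; 1 of 3 day 20 samples above the threshold), OLIG1 24.4-fold (log2 4.61, SE 0.39) and the host transcripts of the microRNA miR-9, MIR9-2HG and MIR9-1HG, 37.3-fold and at least 37.0-fold (3 of 3 and 2 of 3). The pigment cell protein PMEL fell 69.3-fold (log2 -6.12, SE 0.51), FOXA2 was at least 34.5-fold lower (log2 -5.78, SE 0.55) and SIX6 36.5-fold lower (log2 -5.19, SE 0.31). NKX2-1 did not pass limma's test (log2 0.03, SE 0.33, adjusted p = 0.975), and its expression was selected for by the sort on both days.

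Of 20 MGE transcription factors 9 rose and 2 fell (11 and 3 adjusted over the list alone). LHX6, a factor that MGE-derived interneurons keep as they migrate, rose 7.70-fold (log2 2.95, SE 0.32) and DLX5 8.82-fold, while the falls, named after their values were seen, were SIX3 and NKX6-2. The list's median was 0.93, or 0.73 with bounds (limma camera adjusted p = 1.58e-07, and adjusted p = 0.225 with an estimated correlation). In the list for the hypothalamus and other NKX2-1 forebrain 4 of 13 fell and 1 rose (7 and 2 adjusted over the list alone). SIX6, NKX2-2 (10.8-fold), OTP (5.36-fold) and RAX (at least 2.99-fold) were lower, and TRH, named after its value was seen, was higher. Its median was -0.83, or -0.35 with bounds, with 7 negative and 6 positive differences (limma camera adjusted p = 0.00941, and adjusted p = 0.239 with an estimated correlation). Among 10 Hedgehog pathway genes 5 fell (6 adjusted over the list alone), PTCH1 by 6.99-fold (limma camera adjusted p = 5.04e-08, and adjusted p = 0.225 with an estimated correlation); FOXA2 and NKX2-2 stand in this list too. Of 18 interneuron genes 9 rose (10 adjusted over the list alone), with SST at a log2 difference of 3.91 (SE 0.46), RELN 13.5-fold and SLC32A1 4.46-fold higher (limma camera adjusted p = 5.04e-08, and adjusted p = 0.225 with an estimated correlation).

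For neuronal cytoskeleton and differentiation 6 of 30 rose and 1 fell (16 and 2 adjusted over the list alone), GAP43 by 9.20-fold and the neurofilament NEFL by 7.19-fold (limma camera adjusted p = 5.04e-08, and adjusted p = 0.225 with an estimated correlation). In the synapse, receptors and channels list 9 of 36 rose (20 rose and 1 fell adjusted over the list alone), SCN2A by 8.24-fold (limma camera adjusted p = 4.33e-13, and adjusted p = 0.225 with an estimated correlation). Of 8 cholinergic genes 4 rose (5 rose and 1 fell adjusted over the list alone), ACHE by 3.87-fold (limma camera adjusted p = 0.000104, and adjusted p = 0.225 with an estimated correlation). Limma called 0 of 36 cell cycle genes, also adjusted over the list alone, with 1 lower at an unadjusted p under 0.05. The list's median was -0.08 against all 3 day 20 samples and -0.51 against the 1 with a low 28S signal, as at day 55. In the mesoderm and endoderm list 3 of 15 rose and 1 fell (5 and 1 adjusted over the list alone), COL3A1 by at least 12.6-fold (1 of 3 day 20 samples) and DCN by at least 8.43-fold (0.42 without a call for another DCN probe under the authors' filter; limma camera adjusted p = 0.0109, and adjusted p = 0.543 with an estimated correlation). In the astroglia and oligodendroglia list 3 of 14 rose and 1 fell (4 and 2 adjusted over the list alone), the hyaluronan receptor CD44 by a log2 difference of 3.40 (1 of 3 day 20 samples) and APOE by 10.4-fold lower (limma camera adjusted p = 0.457).

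In this comparison 292 genes rose and 128 fell (limma, Benjamini-Hochberg). A bound as fold, with no array of the dimmer day above the threshold, was given for 73 and 24. With values raised to the detection threshold, a setting chosen after seeing the data, 537 rose and 31 fell, so rises made up 94.5% of the calls in place of 69.5%. Of the 420 calls 186 were kept. Genes under the threshold in all 3 day 20 samples have no spread in that setting, so later rises are called more readily. Without day 20 sample 1 the counts were 89 and 31, 251 genes fell without sample 2, and without sample 3 they were 744 and 557. Without sample 1 the MGE list held 6 rises, the interneuron list 3, the synapse list 1, the cytoskeleton list 3, the cholinergic list 2, the astroglia list 1 and the Hedgehog list 2 falls. OTP (log2 -2.51), PTCH1 (-2.72), SLC32A1 (2.05), ACHE (1.93) and APOE (-3.15) had no call then. Without sample 3 the synapse list held 16 rises and the cytoskeleton list 12.

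Day 55 against day 35 compared single samples, on 1 and 2 arrays. Limma called 3 genes (Benjamini-Hochberg), named here after their values were seen; 551 were higher and 523 lower at an unadjusted p under 0.05. DCN, a proteoglycan of connective tissue, rose at least 8.63-fold (log2 3.50, SE 0.27, adjusted p = 0.00945). Under the authors' filter, chosen after seeing the data and without a detection p for day 55, another DCN probe, below the threshold on both days, gave 0.41 (adjusted p = 0.737). RSPO3 was at least 11.7-fold lower (log2 -4.03, SE 0.31, adjusted p = 0.00945) and SIX6 19.8-fold lower (log2 -4.31, SE 0.38, adjusted p = 0.0156). NKX2-1 did not pass limma's test (log2 0.45, SE 0.41, adjusted p = 0.937), and neither did SST (log2 3.21, SE 0.56, adjusted p = 0.138). On both days NKX2-1 expression was selected for by the sort. Cell cycle genes had a median of 2.03 and 36 of 36 were higher at day 55 than on both day 35 arrays. Adjusted over the list alone 27 rose, while limma called 0 over all genes (27 higher at an unadjusted p under 0.05; limma camera adjusted p = 1.51e-33, and adjusted p = 0.406 with an estimated correlation). Over all genes 17 cell cycle genes rose without day 20 sample 2 and 20 without sample 3. The 28S signal differed between these samples (14.96 and 15.01 against 7.46), while the 18S signal was 8.38 and 9.38 against 7.89. Other lists gave 6 rises and 1 fall among MGE factors, 9 and 2 among neural progenitor genes and 0 and 5 for the hypothalamus and other NKX2-1 forebrain, adjusted over the list alone. Their limma camera adjusted p were 5.02e-06, 8.28e-08 and 1.66e-06, each giving an adjusted p = 0.406 with an estimated correlation. The synapse, receptors and channels list (median -0.44) and the neuronal cytoskeleton list (median -0.33) were lower by limma camera, with adjusted p of 0.000525 and 0.00170, and each an adjusted p = 0.406 with an estimated correlation. The 3 calls stood as 7 rises and 8 falls without background correction, 11 and 14 under median scaling, 13 and 20 under cyclic loess, 74 and 45 without day 20 sample 2 and 138 and 99 without sample 3. They stood as 3 and 5 without the first day 0 array, and as 3 and 5 without the first day 35 array. Without sample 1 the count was 1 rise, DCN, and SIX6 and RSPO3 each had an adjusted p of 0.0524 (limma). Without a trend in the variance limma called 0 genes, with unchanged differences and adjusted p of 0.0896, 0.0896 and 0.109 for SIX6, RSPO3 and DCN. With probes detected at all 4 days limma also called 0, and the 3 genes were not among those tested. The authors' filter gave 0 rises and 2 falls by limma.

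For some lists the median, the mean and the direction of camera's test differed in sign, and none of these lists had a camera adjusted p under 0.05. BMP targets had a median of 0.48 and a mean of -0.14 with an upward test at day 20 against day 0, and 0.29 and -0.01 at day 55 against day 0. At day 55 against day 20 the pallium and glutamatergic list had a median of -0.39 and a mean of 0.06 (upward), the neural progenitor and radial glia list 0.06 and -0.09 (downward) and the midbrain, hindbrain and spinal cord list 0.02 and -0.19 (downward). The mesoderm and endoderm list had -0.04 and 0.25 at day 55 against day 0 and -0.25 and 0.10 at day 55 against day 35 (both downward). Neural crest and peripheral neurons gave -0.04 and 0.51 (upward) and astroglia and oligodendroglia 0.01 and 0.09 (downward) at day 35 against day 20. The midbrain, hindbrain and spinal cord list had -0.00 and 0.05 (downward) at day 20 against day 0 and -0.03 and 0.03 (upward) at day 55 against day 35.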

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

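The split between days 55 and 35, the 28S and 18S comparisons, the tests of shared variation, of variation as seen at day 20 and of an NKX2-1 share, the test restricted to genes above the threshold and the authors' filter were chosen after the results were seen. A difference between groups was found for SIX6, RSPO3 and DCN, whose log2 differences from day 0 differed between day 55 and day 35 by -4.31, -4.03 and 3.50 (limma, Benjamini-Hochberg adjusted p = 0.0156, 0.00945 and 0.00945). SIX6 had mean log2 levels of 6.55, 13.21, 12.33 and 8.02 at days 0, 20, 35 and 55. RSPO3 had 6.72, 6.55, 10.19 and 6.16, above the threshold on both day 35 arrays and on 1 of 4 day 0 arrays, and DCN had 6.11, 6.11, 6.26 and 9.76. Without a trend in the variance the differences stayed and no call was left (limma, adjusted p = 0.0896, 0.0896 and 0.109), and without day 20 sample 1 SIX6 and RSPO3 had an adjusted p = 0.0524. Under the authors' filter another DCN probe differed by 0.41 between these days and by -0.50 from day 0, without a call. That filter has no detection p for day 55, so it drops the main DCN probe, detected at day 55 alone. Days 35 and 55 are 1 sample each, so a difference between days was not told apart from a difference between samples. A signal in probes without a single gene name, which the gene counts leave out, was also found. Of 6259 such probes 842 were called between day 35 and day 0, of which 320 rose and 522 fell (limma, Benjamini-Hochberg).

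Cell cycle genes were lower at day 35 than at day 20. Under median scaling and cyclic loess the smaller median was -1.68, which met the condition written beforehand against normalization between arrays as the cause. Both rescale the same arrays, so an error that all scalings share is not excluded. Against the day 20 samples with a high 28S signal the median was -1.76, which does not exclude the 28S signal of the preparation. Those samples read 12.41 and 14.59, below the 14.96 and 15.01 of day 35. In day 20 samples 3, 1 and 2, in order of rising 28S signal, the list's mean level was 10.96, 10.66 and 9.93. Also, 0 day 20 samples had the high 28S and low 18S signal of day 35, which leaves such a preparation open. Variation that the members share between samples is left open. Camera with an estimated correlation gave an unadjusted p of 0.177 (limma), but with 2 residual degrees of freedom that test could hardly decide. An earlier form of that last test, replaced after its value was seen because it ignores shared spread, compared levels. Day 35 then lay 1.28 below the lowest day 20 sample against a range of 1.02 among the day 20 samples, within the bound of 3 ranges set for the level test of the pattern that follows.

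At day 55 against day 20, 4 of 13 genes of the hypothalamus list fell and 1 rose, while 9 of 20 MGE factors rose and 2 fell (limma camera adjusted p = 0.00941 and 1.58e-07, and adjusted p = 0.239 and 0.225 with an estimated correlation). The NKX2-1 difference minus 2 SE was -0.63, above a bound set after the results were seen. A bulk NKX2-1 level does not measure a share of cells, and both days were sorted for the reporter in that gene. A smaller share of NKX2-1 cells was therefore not excluded. The difference between list medians, MGE minus hypothalamic, was 1.55 against the day 20 sample with a low 28S signal. It was at least 1.68 under median scaling and cyclic loess. With genes under the threshold at their bound the 2 medians of the main fit were 0.73 and -0.35. A shift common to both lists cancels in such a difference, and the 28S comparison sets 1 sample against 1. The preparation signal and the normalization are therefore not excluded. The mean level difference at day 55 (2.03) lay 1.95 above the highest day 20 sample, against a range of 0.23 among day 20 samples. Variation that the members share is left open all the same, since day 55 is a single sample. Camera with an estimated correlation gave unadjusted p of 0.0540 and 0.0934 (limma), but with 2 residual degrees of freedom that test could hardly decide.

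Many genes were called between day 20 and day 0, whose arrays had the wider background before quantile normalisation. With values raised to the detection threshold 45.6% of the called genes were still called, which met the bound written beforehand for the background as a cause (under 50%). It is left open because the same setting kept 34.5% of the calls at day 35 against day 20 and 44.3% at day 55 against day 20, comparisons without day 0, a condition added after the value was seen. Among genes above the threshold on every array of both days 18.0% were called (1790 of 9950), against 988 of the other 4034, but the levels themselves make this split, so it excludes nothing.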

How the results depend on the processing

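The settings that raise values to the threshold, use the authors' detection p or fit the 28S signal were chosen after the results were seen. Counts are given as rises and falls in the order day 20, 35 and 55 against day 0, day 35 and 55 against day 20, and day 55 against day 35, and the cause was not tested unless stated. Of 12928 named gene values under 26 other settings 12080 kept direction and call, 393 lost and 453 gained a call, and 2 reversed. An adjusted p under 0.01 and an added log2 difference of 1 kept the main fit, so they could only lose calls. Most named genes were picked for large differences in the main fit, and several settings left out only 1 technical repeat array. Much of this agreement is therefore built in. Losses were 144 of 508 with values raised to the threshold (42 of 104 at day 35 against day 20), 95 at an adjusted p under 0.01 and 73 without day 20 sample 1. MAP4, day 35 minus day 0, was -0.0799 with probes detected at all 4 days. DCN, day 55 minus day 0, was -0.50 with the authors' detection p as filter. In both a different probe of the gene was used. The deposited day averages are means of the same arrays, so they are no test and were left out of these numbers.

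At an adjusted p under 0.01, by construction fewer genes passed, 557 and 560, 845 and 581, 475 and 411, 201 and 79, 66 and 26, with 1 fall in the last comparison. With probes detected at all 4 days, where fewer genes were tested, the counts were 915 and 652, 1150 and 898, 615 and 409, 295 rises, 52 and 42, and 0 and 0 by limma. With the sample as random block over all arrays they were 3212 and 2617, 3474 and 2891, 2539 and 1960, 1619 and 1400, 644 and 506, 250 and 189. All arrays as independent, which takes technical for biological spread, gave 4623 and 3755, 4857 and 4052, 3576 and 2832, 2591 and 2277, 1003 and 807, 578 and 527. Values raised to the threshold gave 647 and 920 at day 20 against day 0, where rises fell to 41.3% of the calls from 55.1%. They gave 1475 and 939 at day 35 against day 0, 626 and 83 at day 35 against day 20 (88.3% rises), 537 and 31 at day 55 against day 20 (94.5%), and 236 and 253 at day 55 against day 35. Genes under the threshold in every day 20 sample have no spread in this setting and are called more readily, which limits what these shares show. The 28S covariate gave 2544 and 1979 at day 20 against day 0 and 2657 and 1996 at day 55 against day 0. It gave 1657 and 1348 and 616 and 421 for days 35 and 55 against day 20, and 63 and 115 at day 55 against day 35. Its slope rests on the 3 day 20 samples alone and takes from the 2 residual degrees of freedom. SIX6 at day 55 against day 20 had a log2 difference of -5.03 with it and -5.19 in the main fit. The added calls therefore do not show that results hold better once the 28S signal is fitted. Median scaling gave 940 falls at day 35 against day 0, 198 at day 35 against day 20, and 11 and 14 in the last comparison. It moved the median of all genes to 0.32, 0.29, 0.21 and 0.17 for day 35 and 55 against day 0 and against day 20, from 0.06, 0.08, 0.01 and 0.01. For day 55 against day 35, rises and falls were 7 and 8 without background correction, 13 and 20 with cyclic loess, 16 and 21 with all probes, 0 and 0 by limma without a trend, and 9 and 11 with the mean of a gene's probes, and the authors' filter gave 0 rises.

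Leaving out 1 array at a time gave rises of 682 to 2375 and falls of 639 to 1925 at day 20 against day 0, 1171 to 2695 and 856 to 2072 at day 35 against day 0, and 668 to 1994 and 558 to 1424 at day 55 against day 0. It gave 206 to 1157 and 84 to 846 at day 35 against day 20, 89 to 744 and 31 to 557 at day 55 against day 20, and 1 to 138 and 0 to 99 at day 55 against day 35. No paired analysis was possible because the labels number a sample 1 at each day and further samples at day 20 alone, so a block for that number leaves no residual degrees of freedom. A slide block was not run since the array names give no slide, and the day averages gave no counts since they hold no replicates. Signal over background limits the folds of dim genes, with an SD of silent probes of up to 0.42 at day 0 before quantile normalisation.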

Other observations

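The gene families here were chosen after the results were seen, as were all genes named from them. All 7 measured metallothioneins, which bind zinc and copper, fell at days 20, 35 and 55 against day 0 (limma, Benjamini-Hochberg), with 6 of 7 called at day 55 under median scaling. MT1E fell 32.8-fold by day 20 (log2 -5.04, SE 0.37) and MT2A had differences of -3.77, -2.41 and -2.13 at the 3 days. No metallothionein was called between the later days. Of the nuclear factor I genes, which act in neural and glial maturation, 3 of 4 rose at days 35 and 55 against day 20, also under median scaling and cyclic loess. NFIB rose 17.9-fold at day 55 against day 20 (log2 4.16, SE 0.35), with mean levels of 9.07, 7.59, 10.45 and 11.75 at days 0, 20, 35 and 55, and NFIA had 6.53, 7.04, 8.74 and 9.60. LIN28A and LIN28B, which block maturation of let-7 microRNAs, both fell at day 55 against day 20 (log2 -4.35 and -1.94).

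The interferon-induced transmembrane genes IFITM1, IFITM2 and IFITM3 all fell at days 35 and 55 against day 0 under each scaling, IFITM1 from 12.47 at day 0 to 7.48 and 7.31. The POU factors of class 3 moved in opposite directions at day 55 against day 20, where POU3F1 fell 18.9-fold (log2 -4.24, SE 0.47) and POU3F2 rose at least 8.64-fold (log2 3.22, SE 0.45; 2 of 3 day 20 samples above the threshold). BCL11A and BCL11B, zinc finger factors of neurons, rose 13.8-fold and at least 13.3-fold (1 of 3 day 20 samples above the threshold) in that comparison, after falls by day 20. BCL11A had mean levels of 11.61, 8.23, 10.97 and 12.02 at days 0, 20, 35 and 55 and did not pass the test at day 55 against day 0 (log2 0.41, adjusted p = 0.616, limma), and POU3F1 had 7.07, 11.55, 8.30 and 7.31. No called member of these families changed sign under another scaling. Of 11 microRNA host genes 4 rose and 2 fell at day 20 against day 0 (limma, Benjamini-Hochberg). MIR100HG was at least 19.2-fold higher, while MIR124-1HG fell 3.48-fold and MIR503HG 1.98-fold. MIR181A2HG had levels of 6.95, 9.96, 12.08 and 9.91 at days 0, 20, 35 and 55. Among 221 named genes tested on the day 0 arrays, 13 (5.88%) had an array past the Dixon limit, where 5% were expected by chance.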
